A study of Mus musculus with 2 samples.

How the data were processed

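The samples were male gonads of MCH mice at embryonic day 14.5 that carried the FLAG-tagged Nanos2 transgene, in 2 groups: RNA from an immunoprecipitation with an antibody against FLAG, and input RNA. Each group had 2 arrays, which the series text calls biological duplicates; the labels describe the RNA extraction in the same words for both groups and give no details of the precipitation. Per the labels' protocols, 0.20 µg of RNA was amplified and labelled with Cy3 for one-colour hybridisation. The arrays were Agilent whole mouse genome arrays, read with Agilent Feature Extraction 9.5 per the submitters' processing notes.

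The deposited scanner files hold, per the file headers, the background-corrected processed signal of each spot as intensity on a linear scale, with a median signal, a local background and marks for spots that are well above background, saturated or outliers. A table of the whole series, deposited by the authors, holds for each probe a ratio of FLAG IP to input, a raw signal per group and a p-value from a t-test whose reference is not given in the sources used here. In the deposited table the raw signal equals the arithmetic mean of the processed signals of the 2 arrays of a group, as checked on the files, so the authors' values are pooled and carry no SD or n; the ratio was used only for comparison, and the deposited p-value was not used. The number of per-sample columns of that table left unused was 0. No reference genome was used, the array headers and the name table refer to different builds, and no coordinates are given.

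Each array held 43379 non-control spots of 41174 probes, and no spot was marked as saturated. The values analysed were log2 of the processed signal minus the 75th percentile over the non-control spots of the array. Spots marked as outliers (61 and 52 on the input arrays, 90 and 104 on the FLAG IP arrays) were set to missing, and spots of one probe were averaged. A probe entered if it was well above background on both arrays of at least 1 group. Where several probes of a gene passed, the one with the highest mean over the 4 arrays stood for the gene. Of the 41174 probes, 31004 were named through their gene ID in the RefSeq gene table of assembly GRCm38.p6, 309 through an older symbol, 1263 kept the name in the file and 8598 had none. This left 15266 genes to test.

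The FLAG IP was compared with the input in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.08 prior ones. Values are log2 fold changes with the moderated SE. Where a gene was not well above background on either array of a group, the fold was given as a bound: the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the gene's own value and the lowest value of any probe well above background there.

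The 24 gene lists, the tests of genes and lists and the rule for the named genes were fixed before the data were examined. The scan of gene groups and some tests of explanations were written after, as stated where they are given. The rule took the 15 largest and the 15 most negative log2 fold changes among genes past the threshold whose FLAG IP arrays both lay on one side of both input arrays, with the higher group well above background on both arrays and a symbol that is not a clone or locus name; Nanos2 and members of the lists could also be named. Some genes that the rule or the lists would name are not reported here. For each list, the median was set against 10000 random lists matched on mean signal in 20 bins, and camera with a preset correlation of 0.01 compared it with all other genes, with adjustment over the lists; camera with an estimated correlation and fry were run beside it.

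The steps were tested on simulated data: 4 arrays were drawn for the 15266 genes of the comparison of FLAG IP against input, with the spread of each group at each signal level, and 200 genes changed. Of 50 genes changed 2-fold 0 were recovered by limma, of 50 changed 4-fold 16, of 50 changed 8-fold 25 and of 50 changed 16-fold 40, and 7 unchanged genes were called. Among simulated lists of 20 genes, camera called 10 of 10 lists shifted 2-fold and 5 of 200 unchanged lists at an unadjusted p under 0.05. Genes were drawn independently there, so this does not test the preset correlation. Only 200 genes changed in the simulation, against 8158 called in the data. The adjustment was therefore stricter there, and the shares recovered do not carry over to the data.

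The alternatives were normexp background correction (offset 50), quantile normalization, median centring, no scaling, no filter on dim probes, a filter on all 4 arrays, the mean of a gene's probes, every probe on its own, marked spots kept, eBayes with trend and robust settings, replicate number as a block, slide as a block, and each array left out in turn. Normexp was planned on the mean signal of each spot and run on the median signal, because the files used here hold only the latter. The authors' own normalized values per array were not used, since the deposited table holds pooled values. Transcript length, GC content and sequence motifs were not analysed here.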

Results

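RNA recovered with an antibody against FLAG from embryonic mouse testis that carried FLAG-tagged Nanos2 was compared with the RNA of the same tissue before immunoprecipitation. Nanos2 is an RNA-binding protein that male germ cells make after they enter the gonad. Male gonads of MCH mice at embryonic day 14.5 carried a transgene that, by its label, joins a Nanos2 enhancer, the FLAG-tagged Nanos2 coding region and the Nanos2 3′ untranslated region. RNA recovered with an antibody against FLAG (FLAG IP) and RNA of the starting material (input) were each hybridised to 2 one-colour Agilent whole mouse genome arrays, so that n = 2 arrays per group, and the series text calls the duplicates biological. No precipitate from gonads without the transgene, or with an unrelated antibody, was analysed here, so RNA that sticks to the beads was not measured.

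The 2 input arrays were close to each other and the FLAG IP arrays differed in brightness. The 75th percentile of the processed signal was 1026 and 1038 intensity units on input replicates 1 and 2, 55.7 on FLAG IP replicate 1 and 608 on FLAG IP replicate 2, a 10.9-fold gap between the FLAG IP arrays before scaling. The brightest spike-in control read 50936 units on FLAG IP replicate 1 and 313830 on FLAG IP replicate 2. Of the non-control spots, 66.0% and 70.2% were well above background on the input arrays, 42.7% on FLAG IP replicate 1 and 65.4% on FLAG IP replicate 2. The median SD between replicates was 0.060 on the log2 scale in the input and 0.304 in the FLAG IP. Across the 15266 genes tested, Pearson's r was 0.997 between the input arrays, 0.963 between the FLAG IP arrays and 0.865 to 0.885 between an input and a FLAG IP array; genes are not independent replicates. The number of arrays, 4 in all, limits the precision of the log2 fold changes that follow, which are FLAG IP over input with the SE from limma.

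The first question was which transcripts the FLAG IP held at a higher or lower share than the input. Nanos2 itself rose by 1.88 ± 0.20 (SE; 3.67-fold, adjusted p = 0.00477), and its single probe does not tell the endogenous transcript from that of the transgene. Among the genes chosen by the fixed rule, Dlx2, a homeobox transcription factor, was not well above background on either input array and stood at least 23.7-fold higher in the FLAG IP (adjusted p = 0.00431). The metabotropic glutamate receptor gene Grm3 rose by 4.58 ± 0.30 (24.0-fold), Hus1b, a paralogue of a DNA damage checkpoint gene, by 4.52 ± 0.27 (22.9-fold), and Gtf2a1l, a germ cell form of a general transcription factor, by 3.90 ± 0.16. At the other end, the embryonic globin gene Hba-x fell by 4.42 ± 0.36 on the log2 scale, and Ptn, which encodes the growth factor pleiotrophin, fell by 3.94 ± 0.20.

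The other genes of that rule covered a narrow range of sizes. Usp44, a deubiquitinase gene, rose by 4.27, the kinase gene Map3k8 by 4.16, the transcription factor gene Grhl1 by 4.14, the neurotrophin receptor gene Ntrk2 by 4.13 and Retreg1, which encodes a receptor of the endoplasmic reticulum, by 3.98. Rab39, a small GTPase gene, rose by 3.94, Pdcl2 by 3.91 and Rspo2, a secreted Wnt agonist gene, by 3.88. Mup10 rose by 4.18, but it belongs to a family of near-identical copies that a probe may not separate. The odorant receptor gene Olfr382, from a large family of related genes, rose by 3.95. For Usp44, Mup10, Map3k8 and Olfr382 only 1 input array was well above background. Among the falling genes, Cdk5r2, which encodes an activator of Cdk5, dropped by 4.72 ± 0.90, with an SD of 1.62 between its input arrays. Tbc1d16 fell by 4.13, the adult globin gene Hba-a2 by 3.98, Eraf, the file's name for the gene of an alpha globin chaperone, by 3.95, Fxyd1 by 3.92, S100a10 by 3.87, the adhesion molecule gene Alcam by 3.81, Tmem256 by 3.80, Hoxd4 by 3.79 and Mical2 by 3.79. The mitochondrially encoded ATP6 transcript fell by 3.83, and Rplp1-ps1, a pseudogene close to a ribosomal protein gene, fell by 3.80. Of these, Cdk5r2, Hba-x, Tbc1d16, Eraf, Fxyd1, Alcam, Hoxd4 and Mical2 were well above background on only 1 FLAG IP array.

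Over all genes, 4275 (28.0%) stood higher and 3883 (25.4%) lower in the FLAG IP at an adjusted p below 0.05 in limma, and 3344 and 3206 of these by 2-fold or more. The median log2 fold change of all genes tested was 0.07. Every called gene had both FLAG IP arrays on one side of both input arrays, which held for 80.2% of all genes tested against 33.3% by chance. Of the genes called lower, 931 were well above background on 1 of the 2 FLAG IP arrays and 23 on neither. Of the 5941 genes with more than 1 tested probe, 119 had probes called in opposite directions. Some genes named in the text had a tested probe that was not called. Among them are Mical2, Lyz2 and Ndufa3, each with 1 of 2 probes called lower, and Parn, with 1 of 2 called higher. The counts moved with single arrays. With the lone array of a group assumed to vary like the other group, limma called 0 genes higher and 0 lower without input replicate 1 (2732 and 2538 at an unadjusted p under 0.05), 1107 and 1237 without input replicate 2, 6577 and 6053 without FLAG IP replicate 1, and 6829 and 5721 without FLAG IP replicate 2. Input replicate 1 lay on a slide of its own and the other 3 arrays on a second slide, and slide as a block left 1431 genes higher and 1545 lower. Of 124 single genes followed across the alternatives, 20 kept their direction but lost their call with that block, and 36 did so with normexp background correction. Of the 8158 called genes, at least 8145 kept their direction without any 1 of the arrays. The separation of the groups in every called gene makes this outcome near certain, so it is not a test of the calls.

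**Figure D1:**
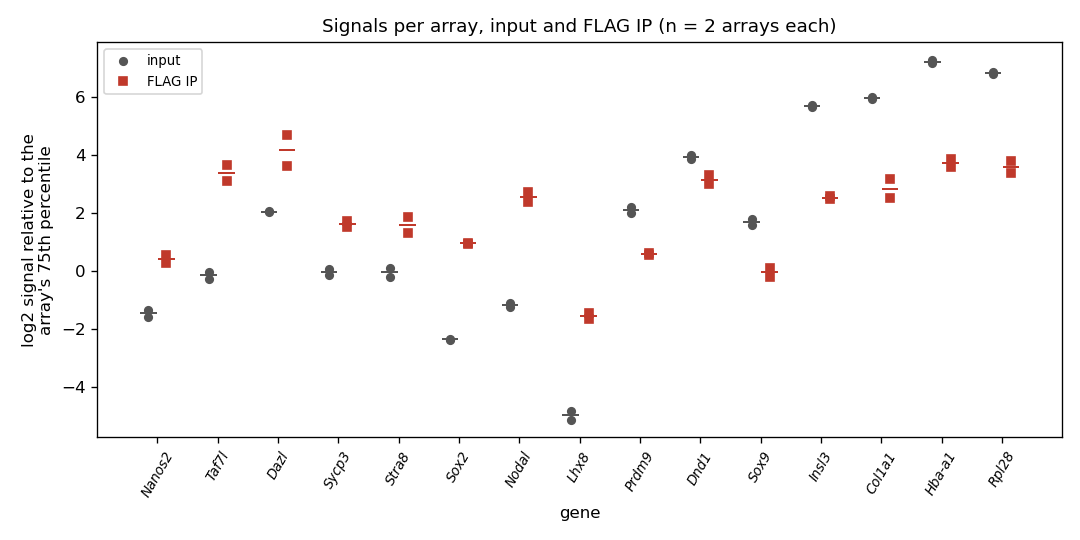
Log2 signal relative to the 75th percentile of each array (vertical axis) for 15 genes (horizontal axis) on the 2 input arrays (grey circles) and the 2 FLAG IP arrays (red squares), with the group mean as a short line. Nanos2, Taf7l, Dazl, Sycp3, Stra8, Sox2, Nodal and Lhx8 lie higher in the FLAG IP, and Prdm9, Dnd1, Sox9, Insl3, Col1a1, Hba-a1 and Rpl28 lie lower.

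Most measured meiosis genes rose. Of 23 measured meiosis genes, 17 rose, 1 fell and 5 did not pass the test, with a median of 1.62 (camera adjusted p = 0.000172, and adjusted p = 0.282 with an estimated correlation), or 0.94 after normexp background correction relative to all genes. Hormad2, Sycp1 and Tex15, which act on meiotic chromosomes, rose by 2.89, 2.47 and 2.45, and Spo11, the gene of the enzyme that makes meiotic DNA breaks, by 1.87. Of the 5 premeiotic genes discussed in the literature as Nanos2 targets, Taf7l rose by 3.53 ± 0.25, Dazl by 2.12 ± 0.41, Sycp3 by 1.68 ± 0.18 and Stra8 by 1.64 ± 0.27, while Prdm9 fell by 1.52 ± 0.17. That list had a median of 1.68 and did not pass the set test (camera adjusted p = 0.132; 0.0279 with no scaling and 0.0211 with every probe on its own), and it is not independent evidence of its direction where that literature drew on these samples. Of 9 oocyte genes, 6 rose, 1 fell and 2 did not pass, with a median of 1.58 (camera adjusted p = 0.0297, and adjusted p = 0.290 with an estimated correlation). The oocyte transcription factor genes Lhx8, Sohlh2 and Figla rose by 3.41, 2.02 and 1.58. The oocyte list no longer passed with no filter on dim probes (camera adjusted p = 0.0527), without FLAG IP replicate 1 (0.0727) or without FLAG IP replicate 2 (0.0783).

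General markers of germ cells and pluripotency went both ways. Of 22 germ cell markers, 11 rose, 4 fell and 7 did not pass, with a median of 0.94 (camera adjusted p = 0.0820). After normexp background correction the median was 0.54 relative to all genes, with 6 markers called higher and 1 lower. The germ cell list did pass with slide as a block (camera adjusted p = 0.0326), without input replicate 2 (0.0203), after quantile normalization (0.0399), with no scaling (0.00762) and with every probe on its own (0.0194). Sox2 and Prdm1, transcription factor genes of primordial germ cells, rose by 3.32 and 3.23, Elavl2, an RNA-binding protein gene, by 3.11 and the helicase gene Ddx4 by 1.69. Dnd1, which germ cells need to survive, fell by 0.78, Ifitm3, a membrane protein gene also active in other cells, by 1.91 and Alpl, the phosphatase gene used to stain germ cells, by 0.82, whereas Pou5f1 stood at -0.01 ± 0.47. Of 17 genes of pluripotency and Nodal signalling, 9 rose, 2 fell and 6 did not pass, with a median of 1.14 (camera adjusted p = 0.0256, and adjusted p = 0.290 with an estimated correlation). The call of this list was lost after normexp background correction (camera adjusted p = 0.0586), with only genes well above background on all 4 arrays (0.0517) and without FLAG IP replicate 2 (0.112), and its median was 0.72 with the mean of each gene's probes and 0.59 with every probe on its own. Nodal, a growth factor gene, rose by 3.74 ± 0.21 and Nanog by 2.59 ± 0.23, while Lefty2, which encodes an inhibitor of Nodal, fell by 2.36 ± 0.21. Adjusted over the list alone, the counts were 12 higher and 4 lower for germ cell markers, and equal to those over all genes tested for the meiosis, premeiotic, oocyte, and pluripotency and Nodal lists.

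Genes of the machinery that Nanos2 is known to work with rose in part. The CCR4-NOT complex, which shortens poly(A) tails, is a known partner of Nanos2. Of 16 genes for this complex and other deadenylation factors, 7 rose, 0 fell and 9 did not pass in limma, with 5 higher and 0 lower adjusted over the list alone. After normexp background correction, 1 of these genes was called higher and 0 lower. Pan3, from another deadenylase complex, rose by 1.67, the deadenylase gene Parn by 1.24 and the scaffold gene Cnot1 by 0.77, whereas Cnot3 stood at -0.24 ± 0.18. The list had a median of 0.71 (camera adjusted p = 0.0325, and adjusted p = 0.290 with an estimated correlation), or 0.44 without FLAG IP replicate 2 and 0.34 after normexp background correction relative to all genes. Its call was lost with slide as a block (camera adjusted p = 0.0671), without input replicate 1 (0.0756), input replicate 2 (0.0718) or FLAG IP replicate 2 (0.183), after normexp (0.191) and with no scaling (0.114). It was also lost with no filter on dim probes (camera adjusted p = 0.0729), with only genes well above background on all 4 arrays (0.0707) and with the mean of each gene's probes (0.0710). Of 22 P-body and decapping genes, 9 rose and 3 fell (camera adjusted p = 0.203, median 0.45, or -0.04 after normexp background correction relative to all genes). Tnrc6a, a gene of the microRNA silencing machinery, rose by 2.17 and Edc3, an enhancer of decapping, by 1.87, while Ago2, the gene of a microRNA effector, fell by 2.26 and Lsm4 by 1.99.

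Of 17 genes for RNA-binding proteins of the germ line, 7 rose and 2 fell, with a median of 0.97 (camera adjusted p = 0.0759), or 0.42 after normexp background correction relative to all genes. Cpeb1, a translational regulator gene, rose by 3.46, the let-7 inhibitor gene Lin28b by 2.69, and Nanos1, a paralogue of Nanos2, by 2.69, whereas Pum2 stood at 0.46 ± 0.73. This list passed with slide as a block (camera adjusted p = 0.0172), without input replicate 1 (0.0279) or input replicate 2 (0.0176), with no scaling (0.00603), with the mean of each gene's probes (0.0273) and with every probe on its own (0.0127). Of 19 genes of the piRNA pathway and de novo DNA methylation, 6 rose, 1 fell and 12 did not pass, with a median of 0.46 (camera adjusted p = 0.127; -0.15 after normexp background correction relative to all genes, and a passing 0.0441 without FLAG IP replicate 1). Henmt1, Tdrd1 and Asz1, genes of piRNA production, rose by 1.36, 1.28 and 0.86, and Dnmt3a, a DNA methyltransferase gene, fell by 0.75. After normexp background correction, 0 genes of the piRNA list were called higher and 0 lower. Adjusted over the list alone, 8 RNA-binding protein genes were higher and 2 lower, and the P-body and piRNA counts equalled those over all genes tested.

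Markers of the somatic cells of the gonad fell. Of 17 Sertoli cell markers, 16 fell and 1 rose, with a median of -2.01 (camera adjusted p = 1.49e-05, and adjusted p = 0.282 with an estimated correlation). Amh, the hormone gene of fetal Sertoli cells, fell by 2.58, Dhh, a secreted signal gene, by 2.91 and the transcription factor gene Sox9 by 1.74, whereas Fgf9 rose by 2.21 ± 0.20. Of 12 Leydig cell markers, 10 fell and 0 rose in limma, with a median of -2.21 (camera adjusted p = 0.000111, and adjusted p = 0.290 with an estimated correlation). Insl3, the hormone gene of Leydig cells, fell by 3.16 and the steroid enzyme genes Cyp17a1 and Cyp11a1 by 2.72 and 2.58. Of 17 markers of interstitial mesenchyme and muscle, 15 fell, among them the collagen genes Col3a1 by 3.42 and Col1a1 by 3.13, with a median of -1.82 (camera adjusted p = 1.72e-05, and adjusted p = 0.290 with an estimated correlation).

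Blood and vessel markers fell as well. Of 14 endothelial markers, 10 fell, with a median of -1.76 (camera adjusted p = 0.000521, and adjusted p = 0.349 with an estimated correlation), and Tie1, a vascular receptor gene well above background on only 1 FLAG IP array, fell by 3.13. Of 11 macrophage markers, 9 fell, such as the lysozyme gene Lyz2 by 2.95, with a median of -2.07 (camera adjusted p = 0.000370, and adjusted p = 0.282 with an estimated correlation). The macrophage call was lost after normexp background correction, where the median was -0.66 relative to all genes (camera adjusted p = 0.284), and with only genes well above background on all 4 arrays (median -1.60, camera adjusted p = 0.216). Of 9 erythroid markers, 7 fell, with a median of -2.45 (camera adjusted p = 0.00138, and adjusted p = 0.290 with an estimated correlation), and the median was -1.54 with no filter on dim probes. Hba-a1, whose near-identical copy Hba-a2 a probe may also read, fell by 3.49. The list of mesonephros and surface epithelium was mixed, with 6 lower and 3 higher of 12 (median -0.97, camera adjusted p = 0.177). Its median was -0.64 without FLAG IP replicate 2, -0.51 after normexp background correction and -1.61 with only genes well above background on all 4 arrays. With every probe on its own the list passed (camera adjusted p = 0.0175). Krt19, a keratin gene, fell by 1.98 and Lhx1, a kidney transcription factor gene, rose by 3.14 ± 0.46. Of 4 measured pregranulosa markers, Wnt4 fell by 2.59 and Rspo1 by 1.71 (median -1.05, -0.41 without input replicate 1 and -0.53 without FLAG IP replicate 1; camera adjusted p = 0.0934). The pregranulosa median was -0.034 with no filter on dim probes (camera adjusted p = 0.419) and -2.15 with only genes well above background on all 4 arrays (0.0571). Adjusted over the list alone, 11 endothelial markers were lower, and the counts of the other somatic lists equalled those over all genes tested.

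**Figure D2:**
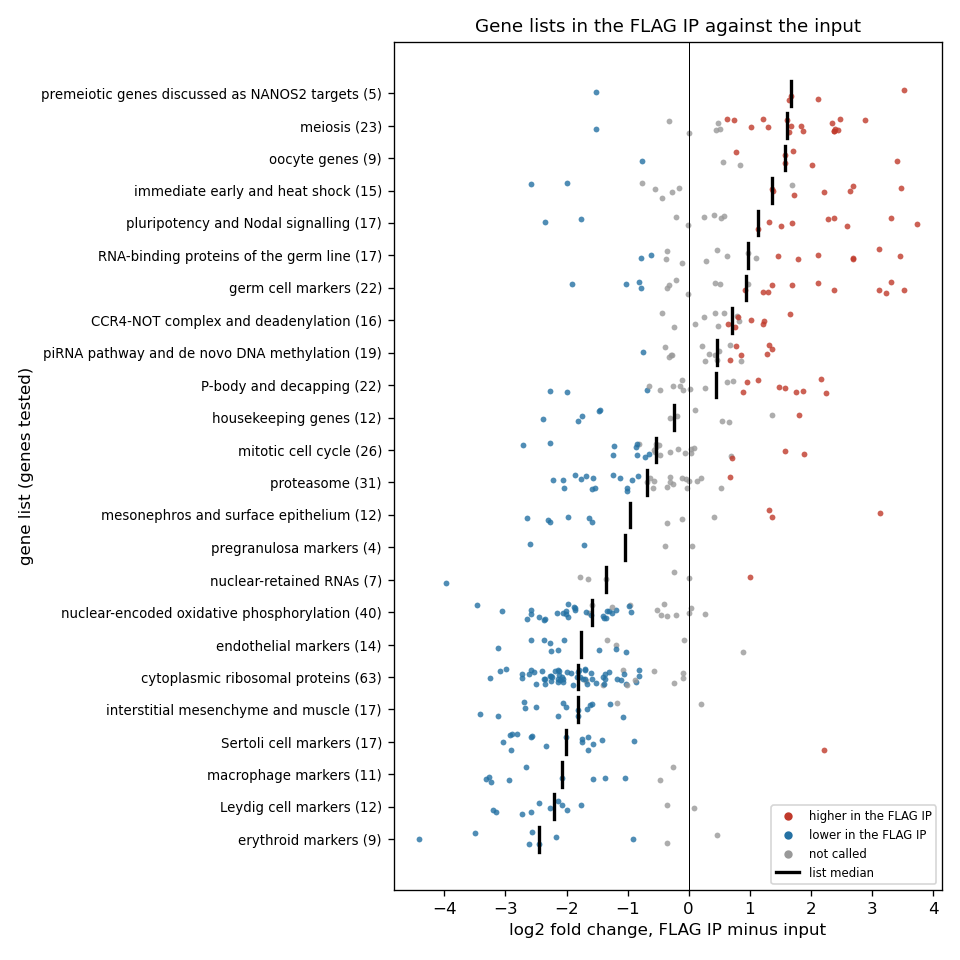
Log2 fold change of FLAG IP over input (horizontal axis) for each tested member of the 24 gene lists (vertical axis, number of genes tested in brackets), coloured by whether the gene was called higher, called lower or not called, with the median of each list as a black bar. Medians run from -2.45 for erythroid markers to 1.68 for the premeiotic genes, with the meiosis list at 1.62 and the Sertoli list at -2.01.

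Ribosomal protein, oxidative phosphorylation and proteasome genes stood lower. Of 63 cytoplasmic ribosomal protein genes, 54 fell and 0 rose in limma, with a median of -1.81 (camera adjusted p = 2.21e-14, and adjusted p = 0.282 with an estimated correlation). Relative to all genes, that median was -1.02 after quantile normalization, where 35 of these genes fell and 2 rose, and -2.67 after normexp background correction, where 34 fell and 0 rose. Rpl28 fell by 3.25 ± 0.21 and Rpl35 by 2.99, whereas Rps3 stood at -0.10 ± 0.16 and was called higher after quantile normalization, at 0.94 (adjusted p = 0.0181); probes for such genes may also read processed pseudogenes. Of 40 nuclear genes of oxidative phosphorylation, 28 fell and 0 rose, with a median of -1.59 (camera adjusted p = 1.11e-08, and adjusted p = 0.290 with an estimated correlation), among them Ndufa3 and Ndufb10, subunit genes of complex I, by 3.47 and 3.06. Of 31 proteasome genes, 15 fell, 1 rose and 15 did not pass, with a median of -0.68 (camera adjusted p = 0.00101, and adjusted p = 0.282 with an estimated correlation; 0.0610 in camera after quantile normalization). The proteasome median was -0.51 after quantile normalization and -1.30 after normexp background correction relative to all genes. Psmb1, a core subunit gene, fell by 2.22 and Psmd1, a subunit gene of the regulatory particle, rose by 0.68.

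Other lists of wide expression were split. Of 26 mitotic cell cycle genes, 9 fell, 3 rose and 14 did not pass (median -0.54; camera adjusted p = 0.0545, but 0.0407 without FLAG IP replicate 1 and 0.0433 without FLAG IP replicate 2). The mitotic list also passed after normexp background correction (median -1.11 relative to all genes, camera adjusted p = 0.00121), with median centring (0.0380), with no filter on dim probes (0.00496), with only genes well above background on all 4 arrays (0.0389) and with every probe on its own (0.0347). After quantile normalization the median was -0.19 (camera adjusted p = 0.304). Ccnd2, a cyclin gene, fell by 2.72 and Bub1, a spindle checkpoint gene, rose by 1.89. Of 15 immediate early and heat shock genes, 7 rose and 2 fell, with a median of 1.37, a median of 0.67 without FLAG IP replicate 1 and no pass in the set test (camera adjusted p = 0.346). Dusp1, a phosphatase gene, rose by 3.48 ± 0.43 and Fos by 2.22 ± 0.25, while the chaperone gene Hspb1 fell by 2.58 ± 0.17. The median of that list was 0.74 after normexp background correction relative to all genes, 0.37 with the mean of each gene's probes and -0.35 with every probe on its own. Of 7 nuclear-retained RNAs, Malat1 fell by 3.97 and Neat1 rose 2.01-fold, with 2 of 4 probes of Malat1 called lower and its reported probe well above background on only 1 FLAG IP array (list median -1.35; camera adjusted p = 0.322). The nuclear list stood at 0.22 without FLAG IP replicate 2, at -0.48 without input replicate 1 and at 0.18 after normexp background correction. It stood at -0.79 with no filter on dim probes and at -0.0027 with only genes well above background on all 4 arrays, and it passed with no scaling (camera adjusted p = 0.0432). Of 12 housekeeping genes, 5 fell and 1 rose (median -0.24, camera adjusted p = 0.282). The median was 0.09 after quantile normalization, -0.15 without input replicate 1, -0.11 without FLAG IP replicate 1 and -0.47 without FLAG IP replicate 2. Ppia fell by 1.82 and the transferrin receptor gene Tfrc rose by 1.80. The housekeeping median was -1.10 after normexp background correction, and it was also below the value given here with the mean of each gene's probes. With every probe on its own it was -1.19 and the list passed (camera adjusted p = 0.0378). Adjusted over the list alone, 57 ribosomal protein, 30 oxidative phosphorylation and 8 mitotic genes were lower, and the counts of the other lists equalled those over all genes tested.

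Of the 24 lists, 13 passed the set test, 4 higher and 9 lower. Of these calls, 0 held in camera with an estimated correlation (unadjusted p under 0.05 for the meiosis list, 0.0456, and the Sertoli list, 0.0359). That version rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. The meiosis list had an estimated correlation of -0.028, below the preset 0.01, yet its unadjusted camera p went from 4.30e-05 to 0.0456. The lost calls therefore do not show that correlation between genes undoes them. Against random lists matched on signal, 7 list medians lay above and 10 below the central 95%, with the meiosis list at percentile 100, the CCR4-NOT list at 93.5 and the proteasome list at 3.64. In fry, which asks only whether the genes of a list move one way on balance, the adjusted p was 0.00343 for the meiosis list and 0.00376 for the Sertoli list. It was also 0.00343 for the P-body list and 0.00538 for the housekeeping list, so fry did not set the former lists apart. Only the mesonephros (0.112), immediate early (0.150) and nuclear-retained (0.193) lists did not pass fry. With slide as a block, all 24 medians kept their sign and 14 lists passed. Input replicate 1 lay alone on its slide, so the block takes up that array. The log2 fold changes are then those of the fit without input replicate 1, apart from which probes enter. All 24 medians kept their sign in that fit too, but the 2 fits are not separate checks. The meiosis median was 1.58, the Sertoli median -2.01 and the ribosomal protein median -1.78 in both.

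The authors' deposited table gives a ratio of FLAG IP over input for each probe. Across the genes tested, its ratio followed the log2 fold changes given here with a Spearman rho of 0.9997, genes not being independent replicates. After each array was centred on its median, 99.3% of the log2 ratios in the authors' deposited table lay within 0.1 of the fold change computed from the arrays. Of the genes called higher, 3006 had a ratio of 2 or more in the authors' deposited table, and of those called lower 3425 had a ratio of 0.5 or less. In the authors' deposited table the ratio was 3.37 for Nanos2, 10.6 for Taf7l and 0.320 for Prdm9.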

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

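Data outside the comparisons of genes also held signal: of 3246 tested probes without a gene symbol, 490 stood higher in the FLAG IP and 515 lower at an adjusted p below 0.05 in limma, fitted on these probes alone, and no explanation was tested.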

How the results depend on the processing

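All alternatives below were planned. The counts of genes higher and lower in the FLAG IP stayed within 1.5 times of 4275 and 3883 under 9 of the 12 alternatives that keep all arrays. Normexp background correction gave 1272 and 1398 and slide as a block 1431 and 1545, and the cause was not tested. No scaling gave 0 and 0 in limma (0 higher and 4047 lower at an unadjusted p under 0.05). It left the 10.9-fold gap between the FLAG IP arrays in the data, and so in their SD. Leaving out 1 array gave 0 to 6829 higher and 0 to 6053 lower genes, with 0 without input replicate 1 and the highest counts in the fits without a FLAG IP array, and the cause was not tested. The number of lists passing ranged from 11 to 19 around 13. The labels give both groups the numbers 1 and 2 without saying that a number marks a shared lysate, and deviations of same-numbered arrays correlated at 0.050 across genes; the replicate block gave 4130 higher and 3875 lower genes, and with it the germ cell (0.0389) and RNA-binding protein (0.0277) lists passed camera.

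The median of all genes moved by 0.31 with normexp, -0.07 with quantile normalization, -0.13 with median centring and -2.49 without scaling, and values under these are given relative to it. Median centring put 47.2% and normexp 47.6% of the calls on the higher side, against 52.4%. Signs turned with normexp for the medians of the piRNA (-0.15), P-body (-0.037) and nuclear-retained (0.18) lists and for Nanos3 (0.32), Rhox6 (0.039), Zp3 (0.57), Pum2 (-0.023), Uqcrc2 (-0.31) and Hprt (-0.62), of which Rhox6 and Zp3 had been called lower; with quantile normalization for the housekeeping list (0.087), Pou5f1 (0.037), Dnmt3l (0.043) and Rps3 (0.94, then called higher); and with every probe on its own for the immediate early list (-0.35). Across the fits without 1 array, Pou5f1 ran from -0.56 to 0.54, Uqcrc2 from -0.034 (without input replicate 2) to 0.094 and the nuclear-retained list from -1.86 to 0.22 (without FLAG IP replicate 2). Pum2 stood at -0.56 and Piwil2 at -1.33 without FLAG IP replicate 2, against 1.48 and 0.76 without FLAG IP replicate 1. The direction of these genes thus depends on which FLAG IP array is kept. The cause was not tested for these. The dim FLAG IP replicate 1, with 42.7% of spots well above background, limits how far low genes can be followed. The authors' values per array were not run.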

Other observations

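Beyond the lists, camera compared 138 groups of genes that share a symbol stem with all other genes. Each group had at least 12 tested members, and the scan was chosen after the data were seen. In it, 11 groups stood higher and 15 lower. In the groups named here no call held in camera with an estimated correlation (adjusted p = 0.694 or more), which with 2 residual degrees of freedom few groups could pass. Of 16 Klf genes, zinc finger transcription factors, 11 rose and 1 fell (median 1.53, adjusted p = 0.0119), with Klf5 at 3.05 and Klf17 at 2.79. Of 38 Zbtb genes, 22 rose and 2 fell (median 1.07, adjusted p = 0.00134), of 47 Usp deubiquitinase genes 29 rose and 3 fell (median 0.82, adjusted p = 0.00134), and of 37 Cep genes of the centrosome 18 rose and 1 fell (median 0.87, adjusted p = 0.00256). These genes were chosen after their values were seen. After normexp background correction the medians, relative to all genes, were 0.91 for Klf, 0.75 for Zbtb, 0.33 for Usp and 0.93 for Cep, and after quantile normalization 1.71, 1.01, 0.88 and 0.80.

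Among the groups that stood lower were the Col, histone and Mrpl genes. Of 39 Col genes, 29 fell and 1 rose (median -1.97, adjusted p = 1.30e-06), and Col27a1 and Col15a1 fell by 3.68 and 3.30. Of 48 histone genes, 32 fell and 0 rose in limma (median -1.88, adjusted p = 4.47e-07), although many of them are near-identical copies. Of 49 Mrpl genes for the large mitochondrial ribosomal subunit, 29 fell and 1 rose (median -1.08, adjusted p = 0.000135). Relative to all genes, the Col, histone and Mrpl medians were -1.81, -1.71 and -1.61 after normexp background correction and -1.92, -1.83 and -0.92 after quantile normalization. Among probes of odorant receptor genes, a family with little known expression in the gonad, 17.4% and 24.6% were well above background on the input arrays, 2.31% on FLAG IP replicate 1 and 16.6% on FLAG IP replicate 2. Of 142 odorant receptor genes tested, 15 rose and 2 fell (median 0.34, camera adjusted p = 0.297). Of 15 vomeronasal receptor genes tested, 6 rose and 0 fell (median 0.97, camera adjusted p = 0.163). The latter median is near the 0.94 of the germ cell markers, and the cause was not tested.

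The tests of signal level, single arrays and replicate error on the germ cell markers were written before their values were seen. So was the test on the separate list of short-lived mRNAs. The other tests in the paragraphs that follow were written after. Germ cell markers had a median of 0.94 although the list did not pass camera (adjusted p = 0.0820) except under some alternatives, such as slide as a block (0.0326). A gain that follows signal level is argued against by the position of that median at percentile 99.6 of random lists matched on signal. The lowest median with each array left out was 0.83, which by the rule written beforehand counts against an origin in 1 array. This outcome was near certain, however. The 11 of 22 markers called higher had both FLAG IP arrays above both input arrays, so they stay above 0 whichever array is left out. No conclusion is drawn from it. A larger share of whole germ cell RNA, with no selection among its transcripts, would move alike the markers that germ cells alone make. Markers also active in other cells, such as Ifitm3, could move otherwise, which limits the comparison. In the planned comparison, their SD of 1.55 exceeded the 0.27 that replicate error gives, with 5 members below 0 by more than 2 SE. By the rule written beforehand this counts against that explanation. Lists of many kinds exceed that error, however, so the result was not taken as decisive. A comparison written afterwards leaves the explanation open, since the SD (bootstrap interval 1.15 to 1.85) is not apart from the SDs of the somatic marker lists, 0.86 to 1.54. Another candidate explanation that stays open is that the FLAG IP held some germ cell transcripts more than others; binding to the beads and a loss that follows transcript length were not tested.

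Ribosomal protein genes stood lower, at a median of -1.81 that, with each array left out, stayed at or below -1.74. Signal level as the whole cause is argued against by its position at percentile 0 of the matched random lists, but its size depends on processing that acts on signal level, with -1.02 after quantile normalization and -2.67 after normexp background correction relative to all genes. Loss of somatic RNA that lowers the genes every cell uses alike stays open, since the ribosomal protein median lay -1.13 from the proteasome median (bootstrap interval -1.59 to -0.61) and -1.37 after normexp background correction (-1.71 to -0.88), but -0.51 after quantile normalization (-1.16 to 0.028). What also stays open is whether the FLAG IP discriminates against these mRNAs, as a hypothesis, or whether short transcripts were recovered or amplified less, which could not be tested without transcript lengths.

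Immediate early and heat shock genes had a median of 1.37, at percentile 99.9 of the matched random lists, and the lowest median with an array left out was 0.67, without FLAG IP replicate 1. The list did not pass camera (adjusted p = 0.346), and its median was 0.37 with the mean of each gene's probes and -0.35 with every probe on its own, so the pattern depends on which probe stands for a gene. The hypothesis that short-lived mRNAs with AU-rich elements may enter the FLAG IP as a class was tested on 23 other such mRNAs: 9 stood higher and 3 lower, with a median of 0.34 at percentile 76.2 of matched random lists. By the rule written beforehand, a median inside the central 95% of those random lists counts against the hypothesis. The members of this separate list went both ways, however, with an SD of 1.22. The result was therefore not taken as decisive, and the hypothesis is left undecided.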
